A study of Mus musculus with 36 samples.

How the data were processed

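Gene expression was measured on Illumina MouseWG-6 v2 bead arrays in inguinal white fat, brown fat and liver of male C57BL/6 mice aged 5 or 24 months. The mice were kept in constant dim red light before harvest, per the labels' protocols. Tissues came from 6 harvest times labelled 0, 4, 8, 12, 16 and 20 h, and the series holds 36 arrays, 1 for each combination of tissue, age and harvest time. The labels give 3 mice for each array and do not state whether their RNA was pooled, so the spread between single mice cannot be read from these data. The sample labels and the design text give an interval of 4 h, whereas the treatment protocol gives 3 h. The times in the sample labels were used. The design text names the white fat depot as inguinal and, in its RNA isolation step, by the abbreviation of another depot. The sample labels name inguinal fat throughout, and that name is used here.

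The deposited values are probe intensities on a linear scale, exported with BeadStudio (version not stated) per the submitters' processing notes. No label states how the background was removed or how the arrays were scaled. The deposited intensity values ranged from -18.1 to 40120, and 28.7 to 29.1% of the values of each array lay below 0, so a background had been subtracted. Sorted by size, the columns of all 36 arrays were nearly identical, so they had been quantile-normalized together across the tissues. Array medians lay between 9.38 and 9.59. Quantile normalization across tissues forces equal distributions on liver and fat, so differences between tissues are relative to that common distribution.

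The design fixed before the data were examined called for normalization of scanner signals with limma's neqc and a filter on detection p-values. A table of scanner signals was deposited too, with 144 columns for 36 arrays. Its array names give the tissue and a running number without age or harvest time, so its columns could not be put to samples and were not used. The deposited normalized intensities took their place as the main values. Values below 0 were set to 0, 16 was added, and log2 was taken. The noise was estimated from the values below 0, mirrored at 0, as an SD of 5.35, and a probe counted as above background on an array above 8.80, the 95% point of that noise. Probes above background on at least 6 of the 12 arrays of a tissue entered the tests. The offset, the floor and this threshold were chosen after the files were seen. Of 45281 probes, 34885 have 1 gene symbol in the platform annotation, 18 have several and 10378 have none. By Entrez number 34807 of the named probes were found in the mouse reference table (assembly GRCm38.p6, used for names only), all with the same symbol. Each gene was represented by its passing probe with the highest mean log2 value in the tissue. A probe without a symbol was tested as a gene of its own and is not named by gene.

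Age was tested within each tissue with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), old minus young, with harvest time as a factor with 6 levels. The harvest time works as a block here, since the labels pair 1 young with 1 old array at each time. Rhythms with a period of 24 h were tested with limma's moderated F test of a cosine and a sine term with age in the model, and a difference of rhythm between ages with the F test of the interaction of age with both terms. Rhythm was also tested in each age on its own terms. The difference of the age effect between tissues and the difference between tissues were tested on the differences of the arrays matched by age and harvest time. The design text says that the tissues were dissected from the same animals. All p-values across genes were adjusted by Benjamini-Hochberg within each test, and the threshold was an adjusted p under 0.05. A rise or fall in the text means a change past that threshold. The amplitude is the fitted distance from mean to peak on the log2 scale, and the peak time counts hours on the scale of the harvest labels. The number of arrays limits the precision: 5 residual degrees of freedom remained for age and 8 for rhythm in each tissue.

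Where every array of 1 group lay below background, the fold is a lower bound: the mean of the brighter group over the background threshold, with the offset added to both.

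A set of 36 gene lists covering pathways and cell types was fixed before the data were examined, and lists with at least 5 measured genes were tested. For age the test was limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists of a tissue. Camera with an estimated correlation and limma's fry, which tests whether a list's genes move on balance in 1 direction and compares no list with other genes, were alternatives. For rhythm the test was a 1-sided Fisher's exact test of the share of rhythmic genes against all other genes tested. Counts of list members "adjusted over the list alone" use Benjamini-Hochberg within that list. The score of a list on an array is the mean log2 value of its measured genes.

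Genes are named by a rule fixed before the data were examined. For age, the 10 largest rises and 10 largest falls in each tissue were named, among genes past the threshold that changed the same way in at least 5 of the 6 harvest times. Where fewer than 3 passed in a direction, the 5 smallest p-values are given as not past the threshold. For rhythm, the 10 smallest p-values and every measured core clock gene were named. For the interactions, the 5 smallest p-values were named, for tissues the 5 largest differences in each direction, and for each list described up to 4 members with the smallest p. The rule did not say whether probes without a symbol take a place, and it was settled after the data were seen that they do not. They would have taken 5 of the 10 places among the rises in inguinal fat and 4 among its falls, 9 among the rises in brown fat, and in liver 9 among the rises and 1 among the falls.

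The fits were tested on simulated data with the real means and spreads of each tissue, with 50 genes changed at each size. Noise was drawn for each gene on its own, so the correlation between genes on the real arrays was left out. Of genes changed with age by a log2 of 0.5, 1, 2 and 4, the test found 26, 82, 100 and 98% in inguinal fat, 28, 80, 92 and 100% in brown fat, and 28, 76, 100 and 100% in liver. Of genes with an amplitude of 0.5 and 1, the rhythm test found 50 and 82% in inguinal fat, 52 and 92% in brown fat, and 48 and 94% in liver. A rhythm of amplitude 1 present at a single age was found by the interaction test in 22% of genes in inguinal fat, 34% in brown fat and 52% in liver, and an amplitude of 2 in 78, 96 and 90%.

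The alternatives covered the filter on dim probes, the probes per gene, the variance model, the form of the harvest time in the model, a fit of all 36 arrays together, the set test, and each harvest time left out in turn. Other offsets and floors, arrays left out, and skeletal muscle or lymphoid transcript scores as covariates were chosen after seeing the data. The 2 ages were split in other ways among the arrays, and the harvest times were reordered, at most 100 times for each test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.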

Results

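Transcript levels were measured on 36 bead arrays from inguinal white fat, brown fat and liver of male C57BL/6 mice, 12 arrays for each tissue. Each tissue was taken from young mice (5 months) and old mice (24 months) at 6 harvest times, 4 h apart by the sample labels, after days in constant dim red light, which removes the light cue to the daily clock. This gives 6 groups of 6 arrays, and no combination of tissue, age and harvest time was measured more than once. The deposited intensities had been brought to 1 common distribution, so each array had nearly the same share of probes above background, 50.8 to 51.1%. The mean correlation of an array with the other arrays of its tissue, both ages together, was between 0.937 and 0.984. The lowest belonged to the old inguinal fat taken at 4 h.

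The difference between tissues was examined first, to show what each dissected tissue held. Brown fat differed most from inguinal fat in Ucp1, the uncoupling protein of thermogenesis, which was 9.17 ± 0.22 (SE) higher on the log2 scale (adjusted p = 1.77e-08), followed by Fabp3 at 7.03 ± 0.62. The muscle myosin light chains Myl2 and Myl3 came next, at 6.84 ± 0.65 and 6.46 ± 0.62, and then the kininogen Kng2 at 6.45 ± 0.12. Inguinal fat exceeded brown fat in lymphocyte genes and a positional gene, with log2 differences, brown minus inguinal, of -5.71 ± 0.35 for Fcmr, -5.49 ± 0.12 for Hoxc9, -5.24 ± 0.29 for H2-M2, -4.90 ± 0.28 for Trbv13-2 and -4.89 ± 0.30 for Ccl5. Ucp1 and Myl3 lay above background on 6 and Myl2 on 8 of 12 inguinal fat arrays, and Hoxc9 on 5, H2-M2 on 6 and Fcmr on 11 of 12 brown fat arrays, so the sizes and order of these differences depend on the offset. Liver exceeded inguinal fat in Mat1a, Ahsg, Ces1c, Cyp2d9 and Fga, by log2 differences of 9.48 to 9.65. The adipocyte genes Aoc3, Lep, Adipoq and Sncg were lower in liver than in inguinal fat, by -9.54 ± 0.22, -9.25 ± 0.13, -9.19 ± 0.30 and -8.66 ± 0.16, and so was Rgcc, by -8.55 ± 0.22. All but Sncg of these 10 genes lay above background on 6 to 9 of 12 arrays in the lower tissue, so this holds for them as well. Against brown fat, liver was higher in the plasma protein genes Ambp, Hpx, Fga, Apoc4 and Ahsg, by 10.29 to 10.49. In brown fat these 5 lay above background on 2 to 6 of 12 arrays, so their sizes and order depend on the offset. Liver was lower than brown fat in Aoc3, Adipoq, Rgcc and Prkar2b, by -8.44 to -8.24. In liver these genes lay above background on 6 to 11 of 12 arrays, so the same limit holds for them. Ucp1 lay below background on all 12 liver arrays, so it was at least 850-fold lower in liver than in brown fat. By limma on arrays matched for age and harvest time, 12475 of 17115 genes differed between brown and inguinal fat (5996 higher and 6479 lower in brown fat), 14155 of 17542 between liver and inguinal fat (6686 higher and 7469 lower in liver), and 12539 of 17270 between liver and brown fat (5703 higher and 6836 lower in liver).

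Transcripts typical of other tissues were present to a changing degree. Skeletal muscle transcripts had a mean log2 value of 12.2 to 13.3 on the brown fat arrays, and of 6.98 to 11.8 on the young and 7.67 to 13.9 on the old inguinal fat arrays. On the liver arrays they ranged from 4.78 to 9.17 in young and from 4.88 to 8.91 in old mice, where 4.00 is the value at an intensity of 0. The T and NK cell list had a mean log2 value of 8.09 ± 0.37 (SD, n = 6) in young inguinal fat, against 5.43 ± 0.72 in young brown fat and 5.10 ± 0.10 in young liver.

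**Figure D1:**
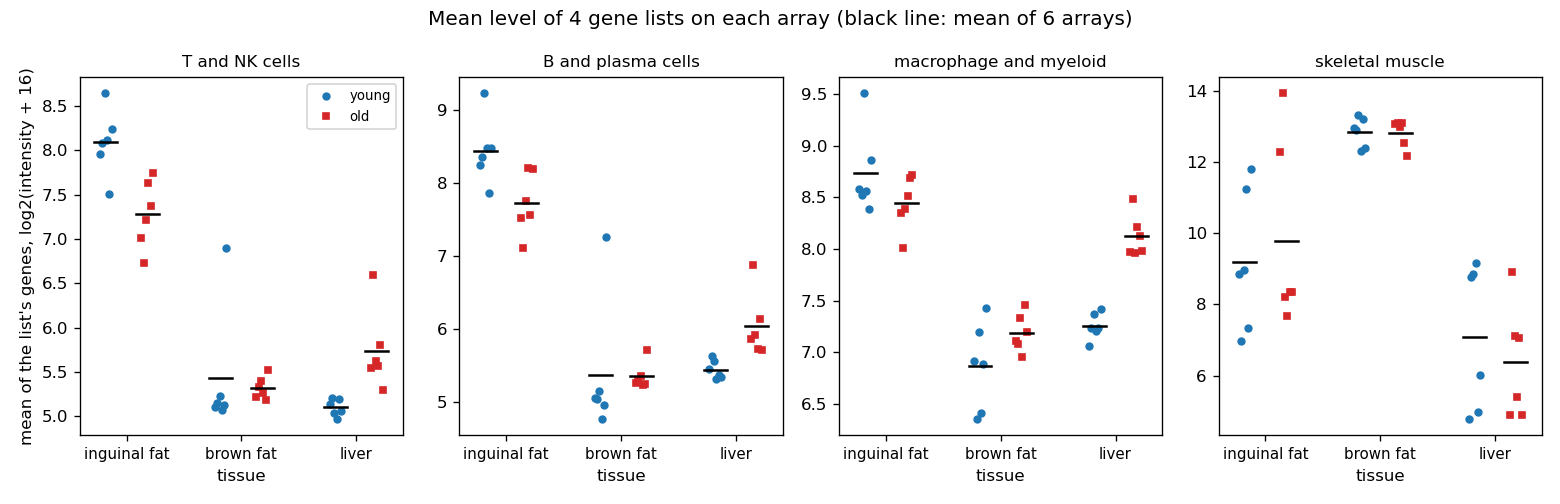
Mean log2(intensity + 16) of the genes of 4 cell-type lists on each array, by tissue and age, with 1 point for each array (blue circles young, red squares old) and a black line at the mean of the 6 arrays. T and NK cell transcripts averaged 8.09 in young and 7.29 in old inguinal fat, and macrophage transcripts averaged 7.26 in young and 8.12 in old liver.

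The age comparison in inguinal fat asks what the 24 month depot expresses differently from the 5 month depot at the same harvest times. Genes of stratified epithelium were among the largest rises. The epithelium and gland list was fixed as a marker of other tissue in inguinal fat. Its score ran from 4.62 to 6.06 on the young and from 5.54 to 7.73 on the old arrays. At 0 h alone it was lower in old mice (5.54 against 6.06). Whether these rises arose in the fat or from a larger share of such tissue in the old samples was not tested. Krt17, a keratin, was 13.8-fold higher in old fat (log2 change 3.79 ± 0.73 SE, adjusted p = 0.0340), Lgals7, a galectin of epithelia, 11.4-fold (3.51 ± 0.78, adjusted p = 0.0470), the gap junction gene Gjb2 9.61-fold (3.26 ± 0.63, adjusted p = 0.0344) and the desmosome gene Pkp1 3.89-fold (1.96 ± 0.41, adjusted p = 0.0416). Ivl, which encodes involucrin, rose by 1.68 ± 0.34 in 5 of 6 harvest times, and Tfap2a, below background on all young arrays, was at least 2.55-fold higher in old fat. Sfrp5, a secreted WNT inhibitor made by adipocytes, rose 3.57-fold (1.84 ± 0.19, adjusted p = 0.0185). C130026I21Rik rose 9.75-fold, Csprs 5.32-fold and 2310011E23Rik by a log2 of 2.11 ± 0.30.

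Lymphocyte genes were prominent among the largest named falls in inguinal fat. The largest was Glycam1, a mucin-like ligand for lymphocyte homing in lymph node vessels, 7.02-fold lower in old fat (-2.81 ± 0.39, adjusted p = 0.0201). The T cell genes Trbv13-2, Cd8b1 and Cd27 changed by -1.67 ± 0.24, -1.57 ± 0.22 and -1.48 ± 0.22 on the log2 scale. For Cd8b1, 1 of 2 other probes above background went the same way. The B cell genes Tnfrsf13c and Vpreb3 changed by -1.52 ± 0.29 and -1.48 ± 0.24, and H2-Ob, of the class II pathway, by -1.45 ± 0.28. Chst3 changed by -1.48 ± 0.23 and the urinary protein gene Mup6 by -1.55 ± 0.33. Ucp1 was above background on all 6 young arrays and on 0 of the 6 old ones, at least 3.06-fold lower in old fat (adjusted p = 0.0425). These 10 falls, and the rises above except Ivl, had the same sign at 6 of 6 harvest times.

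By limma, 670 of 15818 genes passed the threshold in inguinal fat, 194 higher and 476 lower in old mice, and 195 of them were probes without a symbol. The count rested on each harvest time: 0 genes passed without the 0 h pair (2899 at an unadjusted p under 0.05), 207 without 4 h, 140 without 8 h, 39 without 12 h, 416 without 16 h and 91 without 20 h. Without the 0 h pair all 476 falls and 194 rises kept their sign, and the median log2 change of the falls was -0.74 with a median SE of 0.15, against -0.77 with a median SE of 0.13 on all 6 pairs. All 670 were picked on data that include the other 5 pairs and had the same sign in at least 5 of 6. Kept signs and sizes were thus largely fixed in advance and do not offset the loss of calls. With the mean of the lymphocyte lists as a covariate, chosen after seeing the data, 0 genes passed (1825 at an unadjusted p under 0.05), and the median of the falls was -0.36 with a median SE of 0.18. These lists include genes among the falls and their mean differs with age, so part of this loss follows from the choice of covariate.

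**Figure D2:**
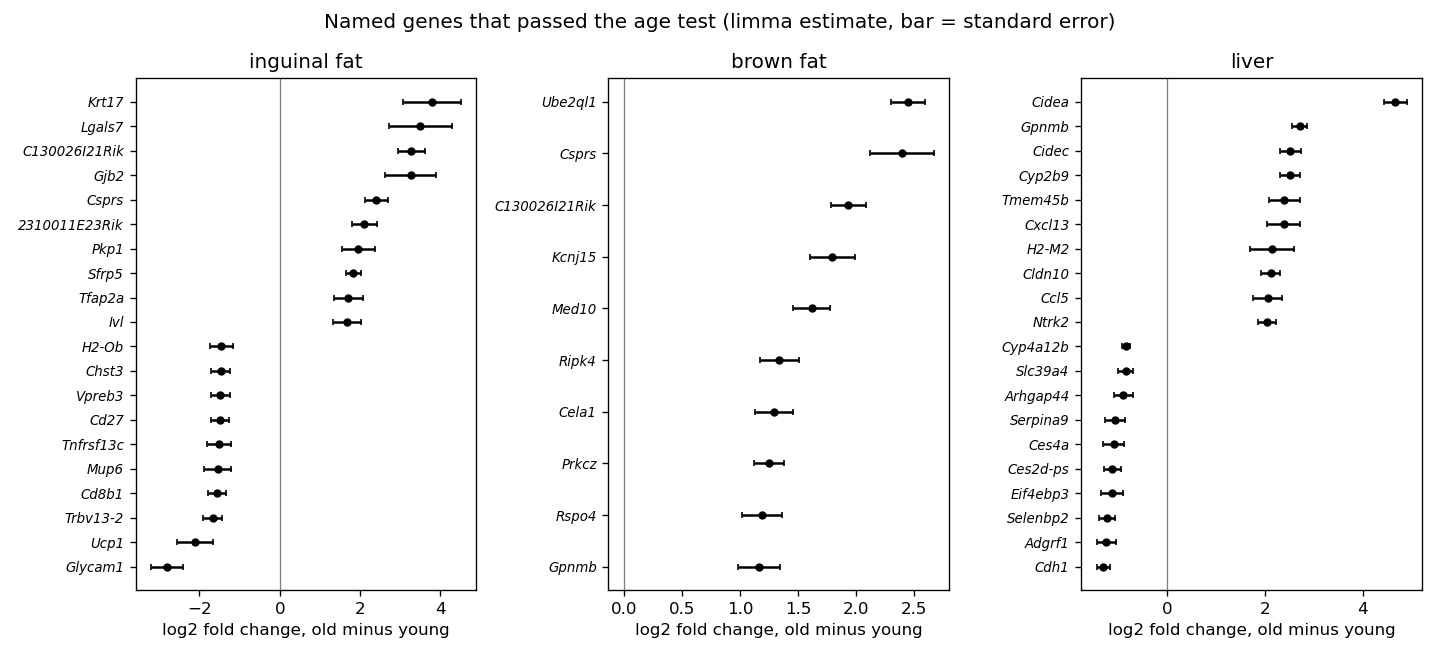
Log2 change with age (old minus young, horizontal axis) of the named genes past the threshold in each tissue, with bars of 1 SE from 6 pairs of arrays. Inguinal fat and liver have 10 rises and 10 falls each, and brown fat has 10 rises.

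Among the gene lists, lymphocyte and antigen-presentation genes were lower in old inguinal fat with a preset correlation between genes, and no list passed with an estimated one (adjusted p from 0.693 to 0.720). Of 17 T and NK cell genes, 9 fell, among them Lat (-1.42), Cd3e (-1.30), Cd247 (-1.29) and Cd8b1, and 13 fell when adjusted over the list alone (median -1.23, camera adjusted p = 7.33e-10). Of 13 B and plasma cell genes, 5 fell and 10 fell adjusted over the list alone, where 1 gene rose (median -0.93, adjusted p = 3.38e-05), with Fcmr at -1.42, Fcrla at -1.39, Cd79b at -1.26 and Cr2 at -0.94. Of 10 class II genes, H2-Ob and H2-Oa (-1.28) fell, 8 adjusted over the list alone (median -0.70, adjusted p = 3.38e-05). Of 19 class I genes 3 fell, Psmb10 (-0.55), H2-Q8 (-0.63) and H2-Q6 (-0.60), and 9 adjusted over the list alone (median -0.40, adjusted p = 1.60e-05). The cell division list had 1 fall of 23, Mcm5 at -0.87, and 11 adjusted over the list alone (median -0.48, adjusted p = 1.60e-05). The interferon list had 1 fall of 24, Ifi47 at -0.89 (median -0.16, adjusted p = 0.0180), also the count adjusted over the list alone. No single gene passed in the macrophage list (24 of 26 lower, 3 adjusted over the list alone, median -0.29, adjusted p = 0.0122) or the ribosomal protein list (21 of 23 lower, 0 adjusted over the list alone, median -0.24, adjusted p = 0.00193).

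Epithelial, white adipocyte and cholesterol synthesis genes stood higher in old inguinal fat with the preset correlation, and with an estimated one these lists did not pass (adjusted p = 0.693). All 12 genes of the epithelium and gland list were higher, with Krt17 past the threshold over all genes and 5 adjusted over the list alone (median 0.92, adjusted p = 5.09e-05). Krt14 was higher by 3.66 but did not pass (adjusted p = 0.120). Of 19 white adipocyte genes 17 were higher, and Mest (1.47) and Hoxc10 (0.58) rose, as they did adjusted over the list alone (median 0.25, adjusted p = 0.00113). In cholesterol synthesis 13 of 16 genes were higher, 0 passed over all genes and 1 adjusted over the list alone (median 0.47, adjusted p = 0.00318), and Lss, a cyclase of the pathway, stood at 1.16 (adjusted p = 0.0525). Lss, Msmo1 and Hsd17b7 were highest on the old 4 h and 12 h arrays, which also had the highest epithelium and gland scores (6.76 and 7.73). In the respiratory chain 31 of 38 genes were higher with 0 past the threshold either way (median 0.09, adjusted p = 0.0165). Of the skeletal muscle genes 19 of 20 were higher (median 0.59), without passing (adjusted p = 0.185). The other lists tested did not pass, with adjusted p from 0.0584 to 0.977, although Gadd45a (0.64), Nr1h4 (0.45) and Aldh1a1 (0.65) rose and Mup2 (-1.33) fell. The median and the test differed in sign for the extracellular matrix and fatty acid synthesis lists, and the median and mean for brown fat thermogenesis, none of which passed. These 12 list calls rest on the preset correlation. With an estimated correlation 0 lists passed (0 at an unadjusted p under 0.05, limma's camera), with adjusted p = 0.693 for 9 of them, 0.716 for the interferon list and 0.720 for the macrophage and respiratory chain lists.

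In brown fat the same age comparison gave rises alone. Ube2ql1, a ubiquitin-conjugating enzyme gene, was 5.45-fold higher in old brown fat (2.45 ± 0.15, adjusted p = 2.22e-04), Csprs 5.26-fold (2.40 ± 0.28, adjusted p = 0.00917), C130026I21Rik 3.82-fold (1.93 ± 0.15, adjusted p = 0.00139) and the potassium channel gene Kcnj15 3.47-fold (1.80 ± 0.19, adjusted p = 0.00811). Med10, a Mediator subunit gene, rose 3.07-fold (1.62 ± 0.16, adjusted p = 0.00506). Ripk4 rose by a log2 of 1.34 ± 0.16, Cela1 by 1.29 ± 0.16, the kinase gene Prkcz by 1.25 ± 0.13 and Rspo4 by 1.19 ± 0.17. Gpnmb, a transmembrane glycoprotein of lipid-laden macrophages, rose 2.24-fold (adjusted p = 0.0370). All 10 were higher in old mice at 6 of 6 harvest times. The lowest p-values among falls did not pass: Zfp619 at -0.61 (adjusted p = 0.0792), the tropomyosin gene Tpm3 at -0.65 (0.105), Hpd at -0.66 (0.114), Adhfe1 at -0.64 (0.166) and Myl3 at -0.60 (0.194).

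By limma, 38 of 15815 genes passed in brown fat, 38 higher and 0 lower in old mice, with 1105 at an unadjusted p under 0.05, and 20 of the 38 were probes without a symbol. The count was 17 without the 0 h pair, 3 without 4 h, 25 without 12 h, 13 without 16 h and 58 without 20 h. Without the filter on dim probes 1 gene passed. With values under 16 set to 16 in place of the offset, a choice made after seeing the data, 4 genes passed.

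Macrophage genes were higher in old brown fat in 23 of 23 cases, with Gpnmb past the threshold over all genes and 5 adjusted over the list alone (median 0.36, camera adjusted p = 1.71e-10). Chemokine and cytokine genes were higher in 15 of 18 cases, 0 over all genes and 4 adjusted over the list alone (median 0.20, adjusted p = 0.00498), and ribosomal protein genes in 23 of 23, with 0 past the threshold either way (median 0.19, adjusted p = 0.00498). With an estimated correlation the adjusted p was 0.839 for all 3 lists. Without the 4 h pair 1 list passed, without 12 h 7, without 16 h 7 and without 20 h 10. The thermogenesis list, with 17 genes, had 0 past the threshold and did not pass (median -0.07, adjusted p = 0.520). Neither did the skeletal muscle list (10 of 21 higher, adjusted p = 0.735) or the T and NK cell list (6 of 13 higher, adjusted p = 0.573). The T and NK cell score was higher in old mice at 5 of 6 harvest times and lower at 20 h alone (5.52 against 6.90 in young mice), and without 20 h, a choice made after seeing the data, 10 of 13 genes were higher (median 0.33). The lists that did not pass had adjusted p from 0.0550 to 0.996, and among them the median and the mean or test differed in sign for white adipocyte identity, Schwann cells and B and plasma cells.

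In liver the largest rise with age was in Cidea, a lipid droplet gene typical of brown fat, 25.3-fold higher in old mice (4.66 ± 0.23, adjusted p = 1.10e-04). The related droplet gene Cidec was 5.75-fold higher (2.52 ± 0.22, adjusted p = 9.52e-04). Gpnmb rose 6.54-fold (2.71 ± 0.15, adjusted p = 1.36e-04), the B cell chemoattractant Cxcl13 5.22-fold (2.38 ± 0.33, adjusted p = 0.00802) and the T cell chemokine Ccl5 4.17-fold (2.06 ± 0.29, adjusted p = 0.00875). Cyp2b9, a cytochrome P450 gene expressed more in female livers, rose 5.72-fold (2.52 ± 0.20, adjusted p = 5.38e-04). The neurotrophin receptor gene Ntrk2 rose 4.13-fold (2.05 ± 0.18, adjusted p = 0.00102). Tmem45b rose by a log2 of 2.40 ± 0.32, H2-M2 by 2.15 ± 0.45 and the claudin gene Cldn10 by 2.12 ± 0.19.

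Falls in old liver were smaller. Cdh1, which encodes E-cadherin, was 2.46-fold lower in old mice (-1.30 ± 0.14, adjusted p = 0.00242), and Cyp4a12b, a male-biased cytochrome P450 gene, changed by -0.84 ± 0.08 (adjusted p = 0.00170). Selenbp2 changed by -1.23 ± 0.17, Adgrf1 by -1.24 ± 0.20, the esterase genes Ces2d-ps and Ces4a by -1.11 ± 0.18 and -1.08 ± 0.21, Serpina9 by -1.07 ± 0.20, Arhgap44 by -0.89 ± 0.19 and the zinc transporter gene Slc39a4 by -0.84 ± 0.15. Eif4ebp3 changed by -1.11 ± 0.22 and was lower in 5 of 6 harvest times, while the other 9 falls and the 10 rises had 1 sign at all 6.

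By limma, 636 of 15813 genes passed in liver, 540 higher and 96 lower in old mice, with 169 probes without a symbol among them. Each harvest time moved the count: 420 passed without 0 h, 369 without 4 h, 393 without 8 h, 282 without 12 h, 310 without 16 h and 415 without 20 h.

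Macrophage genes made up the strongest list in old liver with the preset correlation. With an estimated one none of the following lists passed (adjusted p = 0.253 for macrophages and chemokines and 0.383 for the others). Of 25 genes 17 rose, among them Gpnmb, Ms4a7 (1.94), Clec4n (1.60) and the lipid receptor gene Trem2 (1.51), and 23 rose adjusted over the list alone (median 0.95, camera adjusted p = 1.52e-24). Of 20 chemokine and cytokine genes 7 rose, with Cxcl13, Ccl5, Il1b (1.09) and Ccl2, the last below background on all young arrays, and 13 adjusted over the list alone (median 0.66, adjusted p = 1.04e-09). Of 10 B and plasma cell genes 6 rose, with Mzb1 (1.64), Fcmr (1.43), Cd79b (1.23) and Cd22 (1.05), 7 adjusted over the list alone (median 1.06, adjusted p = 2.18e-06). Of 14 T and NK cell genes 4 rose, Ccl5, Cd3g (1.36), Il7r (1.27) and Klrd1 (1.18), 11 adjusted over the list alone (median 0.87, adjusted p = 1.17e-07). All 10 class II genes were higher, 0 past the threshold over all genes and 10 adjusted over the list alone (median 0.92, adjusted p = 1.17e-07), with Cd74 at 0.90 and H2-DMb1 at 0.72. Of 23 interferon response genes 6 rose, among them Ifi27l2a (0.96), Gbp3 (0.94), Ifi27 (0.76) and Ifit2 (0.72), 13 adjusted over the list alone (median 0.51, adjusted p = 5.15e-08).

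The fibrosis and sex-biased lists had smaller median shifts than the lists above, a difference that was not tested. With an estimated correlation no list that follows passed in camera (adjusted p from 0.253 for male-biased genes to 0.655 for muscle). In the stellate cell list 4 of 14 rose, Cd44 (0.94), Timp1 (0.88), Tgfbi (0.46) and Anxa2 (0.45), and 6 adjusted over the list alone (median 0.31, adjusted p = 3.96e-04). In the extracellular matrix list 3 of 24 rose, Timp1, Dcn (0.47) and Bgn (0.40), and 7 rose and 1 fell adjusted over the list alone (median 0.12, adjusted p = 0.0232). Of 15 male-biased liver genes Cyp4a12b and Selenbp2 fell, and 6 adjusted over the list alone (median -0.27, adjusted p = 2.52e-04), whereas of 9 female-biased genes Cyp2b9 rose, also adjusted over the list alone (median 0.38, adjusted p = 0.0199). The Schwann cell list had 1 rise of 6, Pmp22 at 0.54, and 2 adjusted over the list alone (median 0.32, adjusted p = 0.0278). No single gene passed in the lists of ribosomal proteins (median 0.15, adjusted p = 0.00455, 0 adjusted over the list alone), endothelium (0.17, adjusted p = 0.00860, 2 adjusted over the list alone), cell division (0.15, adjusted p = 0.0199, 0 adjusted over the list alone) or oxidative stress (0.07, adjusted p = 0.0401, 4 adjusted over the list alone), which shifted up, or in the heat shock list, which shifted down (-0.15, adjusted p = 0.0155, 0 adjusted over the list alone). Skeletal muscle genes were lower in 18 of 18 cases (median -0.76, adjusted p = 0.00664), with Tnnc1 (-0.59) past the threshold, also adjusted over the list alone. Among lists that did not pass (adjusted p from 0.0741 to 0.895), Cdkn2a (0.46) rose, and C6 (-0.39), Cyp1a2 (-0.46) and Angptl4 (-0.63) fell, and the median and the mean or test differed in sign for fatty acid oxidation, white adipocyte identity, respiratory chain, erythroid cells, glucocorticoid response and brown fat thermogenesis. With an estimated correlation 0 of the 17 lists passed (4 at an unadjusted p under 0.05, limma's camera). The adjusted p was then 0.253 for the macrophage, chemokine and male-biased lists, 0.383 for the interferon, class II, T and NK cell, B and plasma cell, stellate and Schwann cell lists, 0.391 for female-biased genes and oxidative stress, 0.479 for extracellular matrix, 0.487 for ribosomal proteins and endothelium, 0.593 for heat shock and cell division and 0.655 for muscle. By fry 4 lists moved in 1 direction, macrophage (adjusted p = 0.0143), male-biased genes (0.0171), chemokines (0.0195) and B and plasma cells (0.0338). Without the 8 h pair 10 lists passed.

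Whether ageing acted alike in the 3 tissues was tested on the difference of the age effects. Cidea changed with age by 5.15 ± 0.30 more in liver than in inguinal fat (adjusted p = 2.38e-04) and by 4.73 ± 0.23 more than in brown fat (9.62e-05), and Cidec by 2.39 ± 0.17 and 2.64 ± 0.24 more. The macrophage genes Cx3cr1 and Mpeg1 differed between liver and inguinal fat by 1.67 ± 0.14 and 1.72 ± 0.15, and Pkib by 2.08 ± 0.17. Gprc5b and Ntrk2 rose more in liver than in brown fat, by 1.92 ± 0.17 and 2.15 ± 0.19, while Prkcz, which rose in brown fat, differed by -1.60 ± 0.15. Med10 changed by 1.62 in brown fat and by -0.29 in inguinal fat, a difference of 1.91 ± 0.21 (adjusted p = 0.0490). Between the fats, the macrophage gene Adgre1 (1.10, adjusted p = 0.0715), Lgals7 (-2.81), Mup3 (1.55) and Hspa1a (-1.11, the last 3 with adjusted p = 0.0969) did not pass. By limma the age effect differed in 959 of 14056 genes between liver and inguinal fat (753 higher and 206 lower in liver), in 30 of 14343 between liver and brown fat (23 higher and 7 lower) and in 3 of 14497 between brown and inguinal fat (3 higher in brown fat), Med10 and a pair of probes without a symbol. Exchanging young and old within harvest times gave up to 134 genes for this last comparison. The first count was 391 without 0 h, 348 without 8 h and 463 without 12 h. The second was 17 without 0 h, 9 without 4 h, 15 without 8 h, 14 without 12 h, 11 without 16 h and 16 without 20 h. The third was 0 without 0, 8, 12 or 16 h (1431, 1810, 1847 and 1820 at an unadjusted p under 0.05) and 94 without 20 h.

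The macrophage list differed in its age effect between liver and inguinal fat (median difference 1.43, adjusted p = 2.62e-17, and 0.474 with an estimated correlation), between brown and inguinal fat (0.72, 3.72e-10, and 0.599) and between liver and brown fat (0.56, 4.63e-15, and 0.0955). The lymphocyte genes Cd79b, Cd27, Fcmr, Fcrla, Klrd1 and Cd52 were among 51 genes that changed in opposite directions in liver and inguinal fat, each rising in liver and falling in inguinal fat. C130026I21Rik and Csprs rose in all 3 tissues. Cela1, Kcnj15, Dnajb13 and Nap1l5 rose in both fats, where 12 genes rose in both and 0.383 would if the calls were independent. Gpnmb rose in brown fat and liver, where 17 were shared against 0.841. Liver and inguinal fat shared 11 rises against 4.90 (Fisher's exact p = 0.0101) and 0 falls against 1.90. The tissues came from the same animals per the design text, so whatever sets the young and old animals apart can recur in each tissue. Shared calls are therefore not independent replication.

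Core clock genes were among those with the clearest 24 h rhythms, and the harvest times were fitted with a 24 h cosine in young and old arrays together. In liver Dbp, a clock output gene, had an amplitude of 2.34 ± 0.20 on the log2 scale, or 25.5-fold from peak to trough, and peaked at 8.81 h (adjusted p = 4.85e-04). Ciart had an amplitude of 2.15 ± 0.14 (peak 10.2 h, adjusted p = 1.10e-04) and the clock repressor gene Nr1d1 2.11 ± 0.17 (6.04 h, adjusted p = 3.09e-04), while the activator gene Arntl peaked at 21.2 h (1.66 ± 0.13, adjusted p = 3.07e-04). Usp2 (1.75, 12.1 h), Per3 (1.32, 10.1 h), Per1 (1.10, 12.0 h), Nr1d2 (1.02, 8.12 h), Per2 (0.74, 13.1 h), Tef (0.63, 10.6 h), Bhlhe40 (0.55, 10.2 h) and Clock (0.54, 22.1 h) also passed. Outside the clock list, the mitochondrial protease gene Clpx had the lowest p-value (1.07 ± 0.06, 21.9 h, adjusted p = 8.11e-05), and Lgalsl, Dnmt3b, Tubb2b and Lingo4 were among the first 10. The liver glucose metabolism list held 5 rhythmic genes of 18, 9 adjusted over the list alone (Fisher's exact adjusted p = 4.08e-04), with Ppp1r3c (0.74, peak 22.3 h), Ppp1r3b (0.65, 17.1 h), Pck1 (0.62, 9.94 h) and Gys2 (0.41, 13.4 h). The clock list held 12 of 17, 13 adjusted over the list alone (adjusted p = 7.82e-16), and Rora, Cry2, Hlf, Csnk1d and Csnk1e did not pass. By limma, 320 genes were rhythmic in liver, with a median amplitude of 0.54. Of these 37 peaked from 0 to 6 h, 81 from 6 to 12 h, 80 from 12 to 18 h and 122 from 18 to 24 h. The count was 204 without 0 h, 163 without 4 h, 76 without 8 h, 53 without 12 h and 66 without 20 h, and with 4, 8, 12 or 20 h left out only the clock list passed. Of 18 skeletal muscle genes 0 were rhythmic over all genes, but 16 were when adjusted over the list alone (median amplitude 2.30). With the skeletal muscle score as a covariate, chosen after seeing the data, 112 genes were rhythmic in liver, 106 of them among the 320. A rhythm of muscle transcripts and muscle carried over at some harvest times cannot be told apart here.

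**Figure D3:**
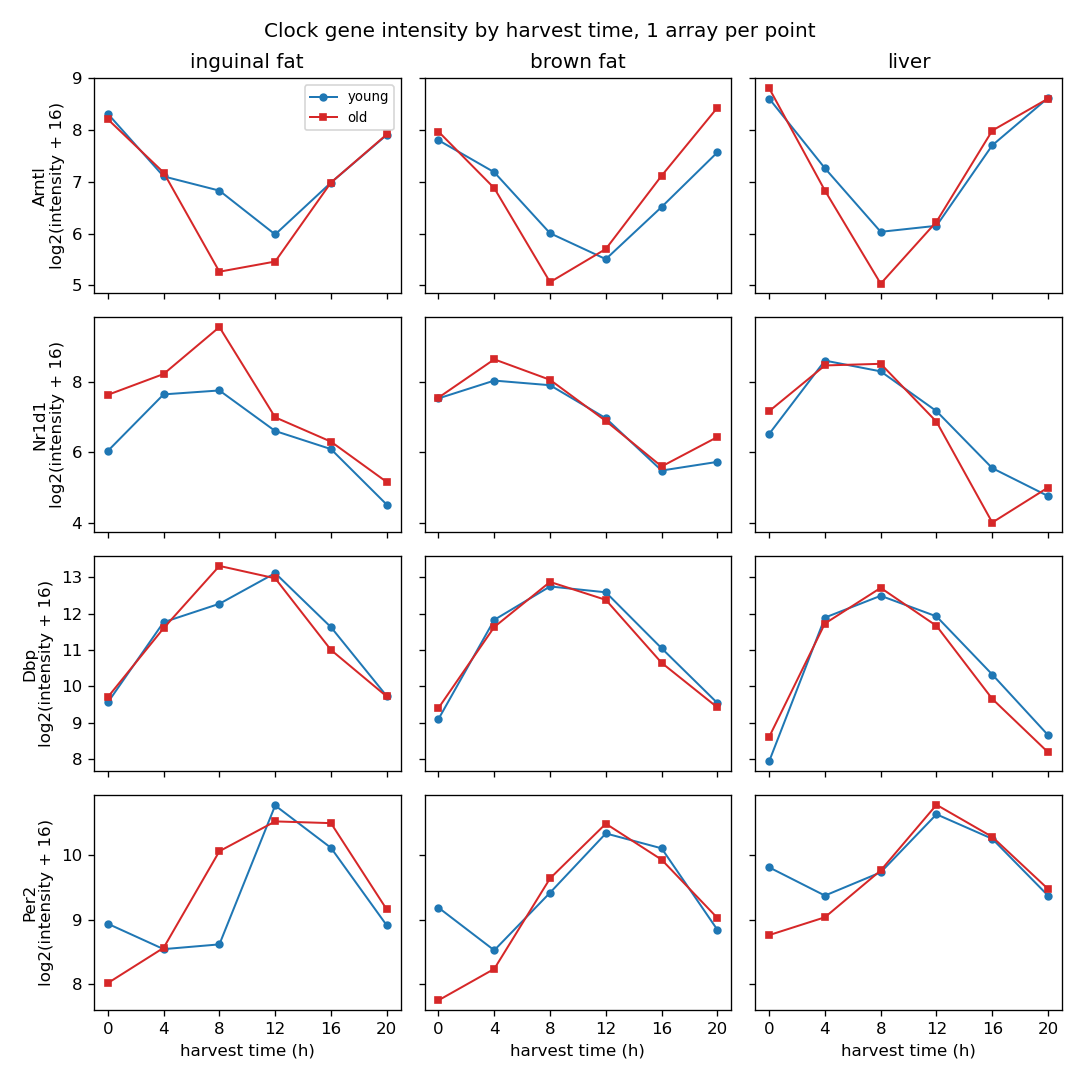
Log2(intensity + 16) of Arntl, Nr1d1, Dbp and Per2 (vertical axis) by harvest time in hours (horizontal axis) in 3 tissues, with 1 array for each point (blue circles young, red squares old). Arntl peaked between 21.2 and 22.5 h and Dbp between 8.81 and 9.87 h by the fits in the 3 tissues.

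In brown fat Dbp (amplitude 1.92 ± 0.11, peak 9.38 h, adjusted p = 4.73e-05), Nr1d1 (1.41 ± 0.10, 5.02 h, adjusted p = 1.45e-04), Ciart (1.55 ± 0.13, 10.1 h, adjusted p = 4.30e-04) and Arntl (1.37 ± 0.14, 22.1 h, adjusted p = 0.00283) were rhythmic, as were Per3 (0.91, 10.9 h) and Per2 (1.07, 13.1 h). The cell cycle gene E2f2 had an amplitude of 1.14 and peaked at 21.8 h, and Osgin1, Dtx4, Coq10b and Vat1l were also among the first 10. The clock list held 6 rhythmic genes of 17, 11 adjusted over the list alone (adjusted p = 3.09e-11), and Tef, Nr1d2, Usp2, Per1, Clock, Rora, Csnk1d, Cry2, Hlf, Csnk1e and Bhlhe40 did not pass. By limma, 35 genes were rhythmic, and 7 without 0 h, 8 without 8 h, 10 without 12 h, 11 without 16 h and 7 without 20 h.

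In inguinal fat Dbp (1.87 ± 0.13, peak 9.87 h, adjusted p = 0.00148), Arntl (1.28 ± 0.14, 22.5 h, adjusted p = 0.0251), Dtx4 (0.93 ± 0.09, 22.7 h, adjusted p = 0.0177) and the vitamin transporter gene Slc5a6 (0.97 ± 0.11, 9.50 h, adjusted p = 0.0251) were rhythmic. H2bc21, the glucocorticoid-induced gene Fkbp5, Osgin1 and the cell cycle inhibitor gene Cdkn1a passed with an adjusted p just under the threshold, whereas Nr1d1 (1.65 ± 0.21, 6.79 h, adjusted p = 0.0506) and Fam110c (adjusted p = 0.0599) did not. The clock list held 2 rhythmic genes of 17, 11 adjusted over the list alone (adjusted p = 0.00136). Of its other genes Per2, Per3, Ciart, Npas2, Per1, Nr1d2, Tef, Clock, Bhlhe40, Csnk1d, Usp2, Rora, Cry2 and Csnk1e did not pass over all genes. By limma, 9 genes were rhythmic, and 0 without 0 h or 12 h (515 and 573 at an unadjusted p under 0.05), 1 without 4 h, 2 without 16 h and 3 without 20 h. Without 0, 12, 16 or 20 h the clock list did not pass either. Arntl, Dbp, Cdkn1a, Dtx4 and Slc5a6 were rhythmic in all 3 tissues. Brown and inguinal fat shared 7 rhythmic genes against 0.0217 for independent calls, liver and inguinal fat 7 against 0.176, and liver and brown fat 17 against 0.602. Calls in tissues of the same animals are not independent, so these values are a description.

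Whether ageing altered these rhythms was tested with the interaction of age and the 24 h terms, and no change was detected. In liver the 12 rhythmic clock genes differed in peak time by a median of -0.215 h, old minus young, from -1.02 h for Nr1d1 to 1.09 h for Bhlhe40. Their median amplitude was 1.04 in young and 1.40 in old mice. In brown fat Arntl peaked at 23.1 h in young and 21.4 h in old mice and did not pass (unadjusted p = 0.00306, adjusted p = 0.920). In liver Pisd-ps2 (amplitude 0.35 in young and 1.18 in old mice), Fmr1nb, Slc35f5, Ciao2a and Slc23a4 had the lowest p-values and did not pass (adjusted p = 0.471). Nor did Ryr2, Jade3, Tes3-ps, Ccdc92b and Csnk1a1 in brown fat (adjusted p = 0.920) or Nono, Cytl1, Tmem123, Phospho1 and Slain1 in inguinal fat (adjusted p = 0.852). By limma, 0 genes passed in each tissue, with 724 in inguinal fat, 749 in brown fat and 1243 in liver at an unadjusted p under 0.05. The interaction test was tried on simulated data without correlation between genes. It found a rhythm of amplitude 1 lost at a single age in 22% of genes in inguinal fat, 34% in brown fat and 52% in liver. By that simulation smaller differences would mostly be missed with 12 arrays. In young mice alone 0 genes were rhythmic in inguinal fat (428 at an unadjusted p under 0.05), 4 in brown fat and 15 in liver, and in old mice alone 0 (1259 at an unadjusted p under 0.05), 5 and 16. The 4 in young brown fat were Dbp, Nr1d1, Arntl and Ciart, which were also among the 5 in old brown fat, with a probe without a symbol. Each of these counts of 4 to 16 moved by more than 1.5 times with any harvest time left out, to between 0 and 7. The 0 in old inguinal fat became 59 without 8 h and 1 without 4 h, and the 0 in young inguinal fat became 1 without 8 h.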

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

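In this part, the tests of muscle dilution in inguinal fat, with and without 8 h, were chosen after the result was seen. So were those of hepatocyte share and blood in liver, of rho in inguinal fat and of the spread of the lymphoid profile. The same holds for B and T cells in SE, the exchange at 20 h, and brown fat and a daily rhythm as sources of muscle transcripts. The tests of lymphoid share, of T and B cells together, of a single liver array, of muscle carry-over and of other splits were set before their own result was seen. Those of lymphoid share, a single liver array and muscle carry-over rest on arrays picked from these data. They were thus not set before the data were examined.

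Single arrays stood apart from the other 5 of their group in the score of a cell-type list or in their mean correlation. That correlation is with all other arrays of the tissue, both ages together. In inguinal fat these were the young 8 h array, with a mean correlation of 0.959, and the old 4 h array, with 0.937. In brown fat they were the young 20 h array, with T and NK cell and B and plasma cell scores of 6.90 and 7.25 where the next highest were 5.23 and 5.14, the old 20 h array with a B and plasma cell score of 5.70, and the young 8 h array with an epithelium score of 4.99. In liver the old 4 h array had a mean correlation of 0.971 and a B and plasma cell score of 6.87. The rule was tried on 12 measures in each of the 6 groups, 72 trials in all, and singled out 8 arrays or scores. Chance singles out about 1 in 20 trials, or 3.60. The measures were read on the same arrays, so the trials are not independent and this number is a rough guide.

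The age effect differed between tissues by the test of the difference. Between liver and inguinal fat it differed for 959 genes, with differences of 5.15 for Cidea, 2.39 for Cidec, 2.08 for Pkib, 1.67 for Cx3cr1 and 1.72 for Mpeg1. Between liver and brown fat it differed for 30 genes, with 4.73 for Cidea, 1.92 for Gprc5b, 2.15 for Ntrk2, 2.64 for Cidec and -1.60 for Prkcz. Between brown and inguinal fat it differed for 3 genes, with 1.91 for Med10. Young and old were exchanged within harvest times in all 32 ways. For the first 2 comparisons 1 way, the real one, gave as many genes (highest other 0 and 0). This argues against chance but does not exclude it, since 1 of 32 is the smallest share this test can give. For brown against inguinal fat 2 of the 32 ways gave as many genes, with 134 genes in the highest other against 3. Chance cannot be excluded there, and so many genes in another arrangement point to a structure of the samples. That arrangement exchanges 20 h alone, and leaving out 20 h gave 94 genes, so the 20 h arrays ran against the other times, among them the young brown fat array with scores of 6.90 and 7.25. Whether that array is the cause was not tested.

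The counts of genes changed with age were set against other splits of the 12 arrays of a tissue. Of 100 splits with harvest time in the model, 1, the real one, gave as many genes in inguinal fat (670, highest other 86), brown fat (38, highest other 3) and liver (636, highest other 1). Of the 32 exchanges of young and old within harvest times, which part as many pairs as the real split, it was also 1 in each tissue, with highest others of 0, 11 and 0. The real split alone reached each count, the smallest share these tests can give, which argues against chance without excluding it. With the harvest times in other orders, 1 of 100 orders, the real one, gave as many rhythmic genes in brown fat (35, highest other 0) and in liver (320, highest other 34). This argues against chance for the rhythms of these 2 tissues too. In inguinal fat 2 of 100 orders gave as many, and the highest other gave 19 genes against 9. Few orders reached the count there, but chance is not excluded for these 9 genes. For rhythms that differ between ages, where 0 genes passed (limma, 724, 749 and 1243 at an unadjusted p under 0.05), the highest other exchanges gave 2, 13 and 199. Against a count of 0 all 32 exchanges give at least as many whatever the data, so this comparison says nothing about chance. With tissues exchanged within age and harvest time, 1 of 100, the real one, gave as many genes for each pair of tissues. The counts were 12475 with highest other 2907, 14155 with 10496 and 12539 with 10416, which argues against chance.

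Lower lymphocyte transcripts in old inguinal fat may come from a lower share of lymphoid tissue, such as the lymph node in this depot, in the old samples. The young 20 h brown fat array, which carried lymphoid transcripts, gave a profile of 87 genes at least 8-fold higher there than in the other 5 young arrays, and 92.0% of them were lower in old inguinal fat, 31 past the threshold, against 52.3% of the other genes, while 160 of the 476 falls were at least 2-fold higher in that array. Since the profile comes from an array picked for its lymphocyte scores, and its changes spread widely (median -0.85, SD 0.58), a lower tissue share and lower expression of these genes cannot be told apart, nor can it be told whether B and T cell lists moved alike (difference 0.977 SD over the 6 pairs, or 2.39 SE). Dilution of the old samples by skeletal muscle is argued against as the sole cause. At 3 harvest times the old array held less muscle (-0.77 at 8 h, -3.62 at 12 h and -3.44 at 20 h). The lymphocyte lists still changed there by -1.76, -0.53 and -0.48, a mean of -0.92, or -0.51 without 8 h, with 28 of 30 genes lower either way. Dilution as a part of the fall is not excluded. At 0 h and 4 h the muscle scores were 12.3 and 13.9 in old against 8.86 and 6.98 in young mice. The T and NK cell scores there were 7.02 and 6.73 against 7.96 and 8.09. At 16 h, with muscle at 8.34 against 7.35, the T and NK cell score was 7.38 against 7.51. Whether the lymphoid share differs through dissection or through ageing of the depot stays open, since no table tells these apart.

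Higher macrophage and lymphocyte transcripts in old liver could arise from a lower share of hepatocytes, which would raise every other cell type alike. The endothelium list had a median change of 0.17 against 0.95 for the macrophage list, with 0 endothelium genes above the macrophage median. This argues against it as the whole cause. Of the endothelium genes 15 of 18 were higher, and of the stellate genes 13 of 14 (median 0.31), against 4 of 7 erythroid genes. A lower hepatocyte share as a smaller part is thus not excluded. Blood left in the old livers is argued against by the erythroid list, with a median change of 0.022. A single old array with lymphoid tissue, such as the 4 h array, is argued against for the macrophage genes, since their median without 4 h was 0.79, and the lists of T and NK cells, B and plasma cells and class II genes had medians of 0.61, 0.97 and 0.67 without it. More or other macrophages and lymphocytes in the ageing liver remain a hypothesis, as does the rise of these genes in cells already there, both untested.

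Skeletal muscle transcripts in some inguinal fat and liver arrays may be carried over from muscle tissue, which was examined in the 6 liver and 4 inguinal fat arrays picked by their muscle score. Across genes, the rise followed the level in brown fat arrays with a Spearman rho of 0.849 in liver (1-sided permutation p = 3e-05, Pearson r = 0.768) and of -0.205 in inguinal fat, and since bright probes alone can give such a rho, carry-over and another cause of the rise cannot be told apart by it. Brown fat as the source is argued against, because Ucp1 stood above background in 0 of these liver arrays (highest intensity 6.01, where the highest Acta1 level would bring 3295 with brown fat) and, though above background in 2 of the 4 inguinal fat arrays, reached at most 228 there, or 1.36% of what the Acta1 level would bring. A strong daily rhythm common to young and old mice is argued against in inguinal fat, where their scores over the 6 harvest times had a correlation of -0.581 (upper limit 0.455 at 2 SE), but a weaker one is not, and in liver, with 0.434 (upper limit 0.925), the question stays open. With both ages fitted together, 16 of 18 muscle genes in liver were rhythmic when adjusted over the list alone. This does not settle it, since carry-over at some harvest times can fit a 24 h cosine too. Carry-over at dissection, in the mouse or on the bench, stays open, and no biological explanation but the rhythm was tested.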

How the results depend on the processing

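In this part, the tests with other offsets and floors, with arrays left out for their quality, and with muscle or lymphoid scores as covariates were chosen after seeing the data. The other alternatives were set beforehand. Of 361 counts under 25 settings, 206 stayed within 1.5 times the reported count and 155 did not. No named gene reversed its sign. With all probes tested, only the probe of a gene with the lowest p was read, so probes of the other sign could be missed. The genes had been named for a change past the threshold with the same sign at most harvest times. With a harvest time left out, kept signs were thus largely fixed in advance and are no test of the changes. Of the values of the named log2 changes, 190 of 354 in inguinal fat and 123 of 167 in brown fat stayed past the threshold. In liver 264 of 329 did, and the others in each tissue fell short of it. Of the clock genes' adjusted p-values, 226 of 248 in inguinal fat, 227 of 254 in brown fat and 228 of 252 in liver stayed on their side of the threshold.

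Without the filter on dim probes, 80 genes changed with age in inguinal fat (65 of them among the 670), 1 in brown fat and 167 in liver, and 0 genes (1502 at an unadjusted p under 0.05, limma), 15 and 147 were rhythmic. In young mice alone 0 (2244 unadjusted) were rhythmic in brown fat and 2 in liver, and in old liver 2. The age effect differed for 0 genes between the fats (3343 unadjusted), 205 between liver and inguinal fat and 1 between liver and brown fat, and 0 lists in inguinal fat and 1 in liver held more rhythmic genes. More genes were tested here. With the strict filter, 21 genes changed with age in brown fat and 563 were rhythmic in liver, 70 in young and 42 in old mice alone, with 10 in old brown fat. The age effect differed for 0 genes between the fats (1866 unadjusted) and 61 between liver and brown fat, and 6 lists changed with age in brown fat. With all probes tested, 8 genes were rhythmic in old brown fat, 0 differed in their age effect between the fats (2801 unadjusted), and 6 lists changed with age in brown fat. For the strict filter and all probes the cause was not tested.

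With a variance trend and robust moderation in limma, 968 genes changed with age in liver, 57 were rhythmic in brown fat and 697 in liver. In young liver 273 were rhythmic, and in old mice 1 in inguinal fat, 13 in brown fat and 168 in liver, while 5 lists changed with age in brown fat and 5 in liver held more rhythmic genes. With a cosine and a sine in place of the harvest time factor, 14 genes differed in their age effect between the fats. With all 36 arrays in 1 fit, 1810 genes changed with age in inguinal fat and 73 in brown fat, and 99, 118 and 563 were rhythmic in inguinal fat, brown fat and liver. With an F test of harvest time in place of the cosine, 0 genes (1143 unadjusted), 6 and 56 were rhythmic, and 0 lists in inguinal fat and 1 in liver held more rhythmic genes. For these settings the cause was not tested.

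With an estimated correlation in camera, 0 lists changed with age in inguinal fat, 0 in brown fat and 0 in liver (0, 0 and 4 at an unadjusted p under 0.05), and with fry 0, 0 and 4 (7, 1 and 16 unadjusted). For the lists called with the preset of 0.01, the estimated correlations ran from 0.0208 to 0.946.

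With an offset of 50, 5, 53 and 582 genes were rhythmic in inguinal fat, brown fat and liver. The age effect differed for 0 genes between the fats (2332 unadjusted) and 72 between liver and brown fat, 7 lists changed with age in brown fat, and 6 in liver held more rhythmic genes. With a floor at 16 and no offset, 4 genes changed with age in brown fat, 1 was rhythmic in inguinal fat and 19 in brown fat, 0 differed in their age effect between the fats (2178 unadjusted), and 1 list in liver held more rhythmic genes. The cause was not tested, though both settings alter how dim values spread.

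With the skeletal muscle score as a covariate, 370 genes changed with age in liver, and 15 and 112 were rhythmic in brown fat and liver. In liver the median of the 540 rises was 0.84 before and 0.86 after, with all signs kept, and the median SE was 0.14 before and 0.15 after, so the calls ended through the wider SE and the degree of freedom spent. With the lymphoid score as a covariate, 0 genes changed with age in inguinal fat (1825 unadjusted). The falls had a median of -0.77 (SE 0.13) before and -0.36 (SE 0.18) after, and the rises 0.74 (SE 0.13) before and 0.65 (SE 0.24) after, so the calls ended through smaller changes of the falls and wider errors of both. The score is built from lists that include genes among the falls, and it differs with age. This outcome follows in part from that and does not show that lymphoid content explains the changes. Without the 4 harvest times with high muscle transcripts in 1 age, 3 genes changed with age in inguinal fat, on 2 pairs of arrays. Without 4, 8 and 12 h, the harvest times with the highest muscle scores in liver, 69 did there on 3 pairs, which keeps the old 16 h array with a score of 7.04. Without the 4 h and 20 h harvest times, 29 genes changed with age in brown fat.

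Leaving out each harvest time in turn, which leaves fewer arrays, gave from 0 to 416 genes changed with age in inguinal fat, 3 to 58 in brown fat and 282 to 420 in liver. Rhythmic genes ranged from 0 to 11, 7 to 25 and 53 to 216, in young mice alone from 0 to 1, 0 to 1 and 0 to 7, and in old mice alone from 0 to 59, 0 to 2 and 0 to 5. Rhythms that differ between ages numbered 0 to 0 in each tissue. The age effect differed for 0 to 94 genes between the fats, 348 to 784 between liver and inguinal fat and 9 to 17 between liver and brown fat. Genes that differ between tissues ranged from 11701 to 12485, 13692 to 14095 and 11931 to 12449. Lists changed with age ranged from 10 to 16, 1 to 10 and 10 to 18, and lists with more rhythmic genes from 0 to 1, 1 to 1 and 1 to 2.

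Without the block of paired harvest times, with age alone in the model, 939 genes changed with age in inguinal fat (582 of the 670 among them), 29 in brown fat and 634 in liver. The age effect then differed for 3, 897 and 26 genes between tissues, and 11, 3 and 16 lists changed.

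Normalization of the scanner signals with neqc within each tissue, for all results and for the levels of named genes, quantile normalization with no background correction, and beadchip as a block were planned and not run, because the columns of scanner signals could not be put to samples. Signal over background limits the dim genes: near 51% of probes lay above background on any array, and folds of genes near it depend on the offset.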

Other observations

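In this part, the test of clock amplitude, the limits of r at 1 and 2 SE and the probe without a symbol were chosen after the result was seen. The test of Cidea against the macrophage score was set before its own result was seen, for a pattern already found in the data.

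A probe without a gene symbol, ILMN_2606313, had the largest rise in inguinal fat, 5.32 ± 0.75 (adjusted p = 0.0201), and rose in brown fat by 3.76 ± 0.42 (adjusted p = 0.00811). In liver it was higher by 1.52 ± 0.39 and did not pass (adjusted p = 0.0763). It was higher in old mice at 6 of 6 harvest times in each tissue.

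The lipid droplet genes Cidea and Cidec rose in old liver, as did 17 of 25 macrophage genes, so Cidea could follow the macrophage score from array to array. No list of lipid droplet genes was tested. Across the 6 old livers Pearson's r was -0.459 (exact 2-sided p = 0.372) and Spearman's rho -0.257 (exact 2-sided p = 0.658), and r was -0.173 without the 2 livers farthest from the median macrophage score. The value of r lies below the bound set beforehand, under which the relation would not hold, by more than 1 SE, which argues against Cidea following the macrophage score closely in these livers. The upper limit of r at 2 SE was 0.578, so a weaker relation is not excluded by 6 livers, and 1 relation of this kind was computed.

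Core clock amplitudes could be larger in old mice, as 11 of the 12 rhythmic clock genes in liver had the larger amplitude in old mice. The median difference was 0.25 on the log2 scale. Among the 32 exchanges of young and old within harvest times 2 gave an absolute median difference as large, the highest other being 0.30, so the question stays open. Of the rhythmic clock genes, 4 of 6 in brown fat and 2 of 2 in inguinal fat had the larger amplitude in old mice.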
